A study of Mus musculus with 6 samples.

How the data were processed

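RNA sequencing was done on DN3 thymocytes of WT and Hspa9 cKO mice, with 3 libraries per group, each in its own table. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted, messenger RNA was enriched either by poly(A) selection or by removal of ribosomal RNA (both are named, and which was used is not given in the sources used here), and random-primed cDNA was amplified and indexed. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1 and the genome build was mm10. The aligner, the transcript assembler, the event caller and the annotation are not given in the sources used here, nor are the Cre driver and any batch or litter.

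Per the file headers, the authors deposited 1 FPKM value per transcript-structure event, of 20 types: transcript starts, transcript ends, skipped exons, retained introns, alternative exons and their counterparts. The FPKM of an event is an estimate for the transcripts that carry it, so it depends on how the authors' software divided reads among isoforms. Events without signal are left out of a table and were set to 0, and such a 0 can be a failed estimate. Gapdh, abundant in most cells, was listed in WT replicate 3 alone, at 0.137 FPKM. The lowest listed value was 1e-06. The tables hold no read counts, so the depth of each library is unknown, no counting interval can be given and tests made for counts were not used. The summed FPKM of start events was 262737, 256513 and 272918 in WT replicates 1 to 3 and 248106, 248014 and 252474 in Hspa9 cKO replicates 1 to 3. Some events are listed more than once within a table, and 0 of the repeated event numbers had differing values.

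The tables group events into assembled loci, some of which join several genes under 1 gene ID. Start and end events were therefore assigned to genes by the exon edge they name, matched to the GENCODE M21 annotation of the same build; 23065 of 27390 start events, with 95.9% of their FPKM, matched the edge of a single gene, 2326, with 1.50%, were placed by the tables' gene ID and overlap, and 1775, with 1.33%, matched none and were left out. All 12288 gene IDs of the tables are in that annotation. A gene's level was the sum of its start events or of its end events: the kind that lists the edge of the principal isoform (as APPRIS marks it), and the kind with the higher mean where both or neither do. Starts were used for 9567 genes and ends for 3042. Of 8104 genes with both sums and a mean of at least 1 FPKM, 56.5% had sums within 10% of each other. Values existed for 11386 of 22028 annotated protein-coding genes; the share was 15.6% among genes with a single annotated transcript and 61.1% among those with several, so the absence of a gene says nothing of its expression.

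Levels were tested on log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), with trended and robust empirical Bayes variances, two-sided, for genes at 1 FPKM or more in at least 3 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design fixed in advance asked for a count test if the tables held counts and for this test if they held FPKM. Gene lists with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, functional and marker lists as separate families. Single values were tested with an exact two-sided permutation test. Named genes were chosen by a rule fixed together with the gene lists: Hspa9 first; the 10 largest called changes in each direction with groups that do not overlap and a mean of at least 5 FPKM; and per list the 2 called members with the smallest adjusted p in each direction, for lists that were called or had at least 3 called members. Some genes that the rule chose are not reported. Members not called are named with values only, and a few further members were named for their values after these were seen (Chac1, Nupr1, Slc7a3 and the markers of other cell types).

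Splicing was examined after the data were seen, since the tables hold events. Inclusion and exclusion events that share both flanks were paired, and log2((inclusion + 1)/(exclusion + 1)) was tested with limma for pairs with a mean total of at least 5 FPKM. The tests were tried on simulated data. With 200 of 9612 simulated genes changed, 17.9% of the genes changed by 0.5 on the log2 scale were recovered, 62.7% of those changed by 1 and 92.4% of those changed by 2, with 6 false calls among 121. A list of 30 genes shifted by 0.5 was called and 0 of 20 unshifted lists were. The simulated genes varied independently of each other, so this does not show how often unshifted lists of correlated genes would be called. For 10573 splicing ratios, 32.0% of 200 simulated changes of 3 on the log2 scale were recovered, with 6 false calls.

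The alternatives fixed in advance were a replicate block, other filters (none, and 5 FPKM), a pseudocount of 0.1, rescaling by trimmed means of log ratios (30% of ratios and 5% of levels trimmed at each end, unweighted since FPKM carry no counts) or by median ratios, leaving out each library, a test against a 1.2-fold change, and for the lists other correlations. Added after the data were seen were start events alone, end events alone, grouping by the tables' own gene IDs, genes with a listed principal edge alone, and removal of each library's loess trend (span 0.5) over transcript length and GC content. Tables were read with Python 3.11.15 and pandas 2.3.3.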

Results

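Messenger RNA was profiled in DN3 thymocytes, the early T cell precursors in the mouse thymus that carry CD25 but not CD4, CD8, CD44 or markers of other lineages and that rearrange the T cell receptor beta chain. The cells were sorted from WT mice and from Hspa9 cKO mice, all 5 weeks old, to ask what GRP75 does in early thymocyte development. Hspa9 encodes GRP75, also called mortalin, the HSP70 chaperone of the mitochondrial matrix, which takes part in protein import and folding. Each group held 3 libraries, and the labels do not say whether each came from a separate animal, so p-values measure only the spread between these libraries, which may be technical. The deposited values are FPKM, fragments scaled to transcript length and library size, of transcript-structure events. Read depth is unknown because the tables hold no counts. The WT libraries listed 89771, 88193 and 87403 distinct events and the Hspa9 cKO libraries 90561, 90970 and 90824. A gene's level was the summed FPKM of its transcript starts or of its transcript ends, whichever was fixed for that gene in all 6 libraries. This gave values for 12609 genes, and 9612 of them, at 1 FPKM or more in at least 3 libraries, were tested. Pearson correlations of log2(FPKM + 1) across genes lay between 0.958 and 0.965 within groups and between 0.937 and 0.941 across groups; genes are not independent replicates.

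The first comparison asked whether the targeted gene itself differed between the groups. The total Hspa9 level did not differ by more than its spread, but the structure of its transcripts did. Hspa9 (ENSMUSG00000024359; mm10 chromosome 18, 34937414 to 34954357, minus strand) stood at 105.4, 121.2 and 121.7 FPKM in WT replicates 1, 2 and 3 and at 117.2, 123.5 and 109.7 FPKM in Hspa9 cKO replicates 1, 2 and 3. The log2 change was 0.01 with a standard error of 0.09 (limma, adjusted p = 0.952; exact two-sided permutation test, p = 0.8). The event that joins exon 1 to exon 5 through exons 2, 3 and 4 was at 106.3 ± 2.25 FPKM (SD, n = 3) in WT and at 22.3 ± 4.78 FPKM (SD, n = 3) in Hspa9 cKO. The event that joins exon 1 directly to exon 5 was not listed in WT replicate 1, stood at 12.3 and 17.0 FPKM in WT replicates 2 and 3 and at 76.9, 89.4 and 68.9 FPKM in the Hspa9 cKO libraries. A second skipping event, which enters exon 5 at an acceptor 4 nucleotides further in, was listed in each Hspa9 cKO library, at 15.3, 17.3 and 15.6 FPKM, and in no WT library. Transcripts that included the 3 exons made up 92.0% ± 7.21 (SD, n = 3) of the total over these events in WT and 19.3% ± 4.99 (SD, n = 3) in Hspa9 cKO. All 3 libraries of one group lay apart from all 3 of the other, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Among all paired splicing ratios, that of the including event to the first skipping event was not called (limma, log2 ratio change -5.90, standard error 1.16, adjusted p = 0.222). This ratio leaves out the second skipping event, and the skipping event not listed in WT replicate 1 entered it as 0.

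Exons 2, 3 and 4 lie on chromosome 18 at 34952677 to 34952735, 34952396 to 34952483 and 34951224 to 34951405, and all are coding sequence in the principal isoform, which has 17 exons. Together they are 329 nucleotides long, which is not a multiple of 3, while skipping to the second acceptor removes 333 nucleotides, which is. The protein was not measured.

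**Figure D1:**
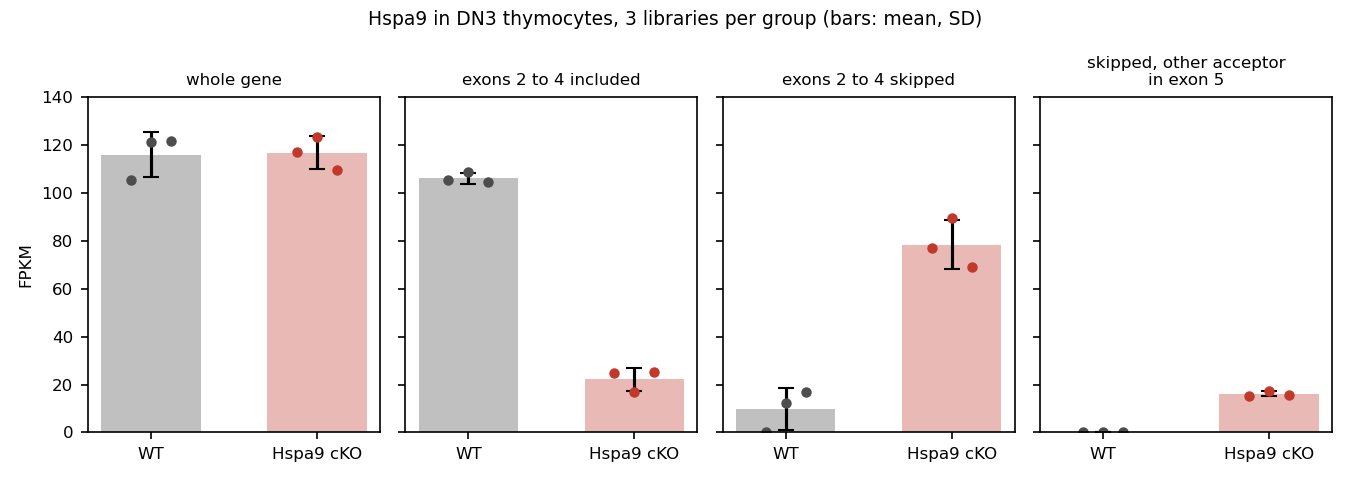
Hspa9 FPKM (vertical axis) for the whole gene, for the event that includes exons 2 to 4 and for both events that skip them; points are libraries, bars are means and error bars are SDs of 3 libraries. The whole-gene panel overlaps between groups, and the event including the 3 exons falls from a mean of 106.3 FPKM in WT to 22.3 FPKM in Hspa9 cKO.

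The second comparison asked which other genes differed between Hspa9 cKO and WT. Of the 9612 genes tested, 814 were higher and 530 lower in Hspa9 cKO at a Benjamini-Hochberg adjusted p under 0.05 (limma, two-sided). After rescaling the libraries by trimmed means of log ratios the same test gave 656 higher and 659 lower, and after rescaling by median ratios 668 and 644, so the balance of directions depends on the scaling. Among the called genes, 177 were at least 2-fold higher and 46 at least 2-fold lower on the log2(FPKM + 1) scale, which understates the change of low genes. All 1344 called genes had the 3 Hspa9 cKO libraries on one side of the 3 WT libraries, an arrangement that chance alone gives for 10% of genes and that 39.0% of the tested genes showed. The count of called genes was 587, 882 and 789 without WT replicate 1, 2 or 3, and 559, 597 and 521 without Hspa9 cKO replicate 1, 2 or 3.

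The largest increase was in Cox6a2, the heart and muscle isoform of a cytochrome c oxidase subunit, which went from 0.590 ± 0.102 FPKM (SD, n = 3) in WT to 47.1 ± 15.6 FPKM (SD, n = 3) in Hspa9 cKO, a log2 change of 4.87 with a standard error of 0.22 (limma, adjusted p = 0.000569). From its transcript ends the log2 change of Cox6a2 was 2.49. Trib3, a pseudokinase induced by amino acid and endoplasmic reticulum stress, rose by 4.24 on the log2 scale, Asns (asparagine synthetase) by 3.26, Atf5, a transcription factor of the mitochondrial stress response, by 3.02, and Eif4ebp1, a repressor of cap-dependent translation, by 1.99. Oasl2 and Ifit1, both induced by interferon, rose by 2.18 and 2.03. H2-Q6 and H2-Q5, class Ib histocompatibility genes, rose by 2.32 and 2.21, but these are near-identical paralogs whose reads the authors' processing could have split between them, so each value is uncertain. The long noncoding transcript 2700054A10Rik rose by 2.09. The largest decreases were in Mir142hg, the host transcript of a blood cell microRNA, with a log2 change of -3.03, and in Sik1, a salt-inducible kinase, which went from 48.6 ± 8.06 to 5.64 ± 1.77 FPKM (SD, n = 3 each), a log2 change of -2.93. Fosb, a subunit of the AP-1 transcription factor, changed by -2.26, Klf4, a transcription factor that restrains proliferation, by -1.96, Mbnl3, a splicing regulator, by -1.71, Tnfaip3, the inhibitor of NF-kB known as A20, by -1.68, Cdc26, a subunit of the anaphase-promoting complex, by -1.66, and Trib1 by -1.59. Pgam1, a glycolytic enzyme, changed by -2.01 and the tubulin gene Tuba1a by -1.87. The calls of Pgam1, Mir142hg and Tuba1a were lost when single libraries were left out (for Pgam1 any library but Hspa9 cKO replicate 1; for Mir142hg WT replicate 1 or any Hspa9 cKO library; for Tuba1a Hspa9 cKO replicate 1 or 2), and from its transcript ends Tuba1a had a log2 change of 0.18, and with the tables' own gene IDs -1.05. With a pseudocount of 0.1 the log2 changes of Trib3 and Mir142hg were 6.94 and -5.17.

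The third comparison asked whether 32 functional gene lists, fixed before the data were examined, moved as groups. Of these, 30 had at least 5 tested members and 18 were called, 5 upward and 13 downward (limma camera with an inter-gene correlation of 0.01, adjusted p under 0.05). With a correlation estimated for each list, 6 of the lists were called: mitosis, type I interferon response, S phase, MYC targets, cytosolic heat shock and cholesterol synthesis. fry, which asks only whether a list's genes move one way, called 22. It did not call cytosolic ribosomal proteins (adjusted p = 0.0681), and it called 5 lists that camera did not: p53 targets (0.000614), the pre-TCR signal response (0.00342), mitochondrial dynamics and mitophagy (0.00648), DN1 and DN2 progenitor genes (0.0071) and pyroptosis and necroptosis (0.0243). The 13 mitochondrially encoded genes were not measured, and of 22 histone genes 1 was, so these lists were not tested.

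The type I interferon response rose. Of its 39 tested members 32 were higher and none lower, with 7 not called; adjusted over the list alone, 35 were higher and none lower. The median log2 change was 1.17 (limma camera, adjusted p = 2.59e-21; adjusted p = 0.00492 with an estimated correlation). Ifit1 went from 1.62 ± 0.0818 to 9.69 ± 0.124 FPKM (SD, n = 3 each). Rtp4, a receptor-transporting protein induced by interferon, went from 8.40 ± 1.12 to 32.5 ± 3.57 FPKM (SD, n = 3 each), a log2 change of 1.84 (limma, adjusted p = 0.00133). From its transcript starts Rtp4 had 3.97. Mx1 and Ifi204, of the same list, were not listed in the 3 WT libraries, which can be a failed estimate; Mx1 was at 1.93, 2.24 and 2.82 FPKM and Ifi204 at 1.39, 1.28 and 1.49 FPKM in Hspa9 cKO replicates 1 to 3. The sensors of cytosolic nucleic acid rose with a median log2 change of 0.54, 6 of 11 members being called higher, 6 also when adjusted over the list alone, and none lower (camera, adjusted p = 0.00163; adjusted p = 0.0726 with an estimated correlation). Of these, Zbp1, a sensor of Z-form nucleic acid, had a log2 change of 1.06 and Eif2ak2, the kinase PKR, of 0.87; 3 members, Zbp1, Ifih1 and Ddx58, also belong to the interferon list.

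The integrated stress response, the targets of the transcription factors ATF4 and CHOP, rose as well. Of 25 tested members 14 were higher, 1 was lower and 10 were not called; adjusted over the list alone, 15 were higher and 2 lower. The median log2 change was 0.43 and the mean 0.91 (camera, adjusted p = 9.19e-06; adjusted p = 0.0515 with an estimated correlation). Asns went from 1.11 ± 0.122 to 19.3 ± 1.29 FPKM and Atf5 from 5.23 ± 0.365 to 49.7 ± 3.47 FPKM (SD, n = 3 each; limma, adjusted p = 0.000185 for both). Chac1, Nupr1 and Slc7a3 were not listed in the 3 WT libraries, which can be a failed estimate, and stood between 2.44 and 3.99 FPKM in the 3 Hspa9 cKO libraries. Ppp1r15a, which reverses the translational block of this response, was the member called lower, with a log2 change of -0.44; its call was lost without any single library except WT replicate 2.

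**Figure D2:**
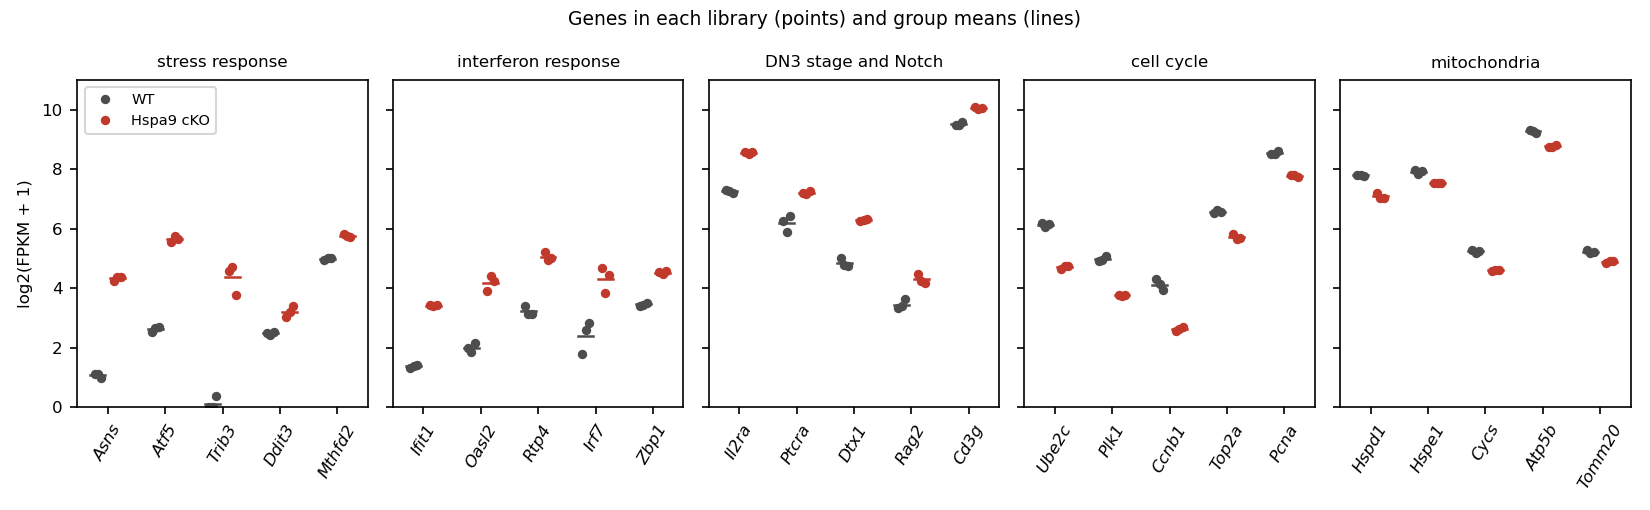
Log2(FPKM + 1) of 25 genes (horizontal axis) in each library; points are libraries and lines are means of the 3 libraries of each group. The genes shown of the stress and interferon responses and of the DN3 stage lie higher in Hspa9 cKO (log2 change 3.26 for Asns). Those shown of the cell cycle and of mitochondria lie lower (-1.41 for Ube2c). The selection does not stand for whole lists: some genes lie outside the naming rule, and members called the other way, such as Dntt and Ppp1r15a, are not shown.

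Other protein-folding lists did not rise with it. Of 10 cytosolic heat shock genes 6 were lower and none higher, 7 lower when adjusted over the list alone, with a median log2 change of -0.48 (camera, adjusted p = 1.57e-05; adjusted p = 0.0438 with an estimated correlation). Hsp90aa1 changed by -0.69 and the co-chaperone Dnajb1 by -0.94. Of 17 mitochondrial chaperones and proteases 4 were lower and none higher, 7 lower and 1 higher when adjusted over the list alone, with a median log2 change of -0.21 (camera, adjusted p = 0.0131; adjusted p = 0.124 with an estimated correlation). Hspd1, the matrix chaperonin HSP60, went from 222.1 ± 2.73 to 135.5 ± 9.08 FPKM (SD, n = 3 each), a log2 change of -0.71 (limma, adjusted p = 0.00404), and its partner Hspe1 changed by -0.38, a call lost without WT replicate 1 or any 1 Hspa9 cKO library; after removal of the trend over transcript length and GC content Hspe1 had -0.25. The endoplasmic reticulum unfolded protein response was not called (camera, adjusted p = 0.785), with 4 of 20 members higher and 2 lower, 6 and 4 when adjusted over the list alone. Its median was -0.01 and its mean 0.09. Xbp1 and Herpud1, of this list, had log2 changes of 1.12 and 1.1, while the chaperone Hspa5 and its cofactor Dnajb9 had -0.47 and -0.99.

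Cell cycle genes fell. Of the 34 genes of mitosis and G2/M 26 were lower and none higher, 31 lower when adjusted over the list alone, with a median log2 change of -0.83 (camera, adjusted p = 9.01e-24; adjusted p = 0.00492 with an estimated correlation). Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 69.4 ± 3.30 to 25.5 ± 0.961 FPKM (SD, n = 3 each), a log2 change of -1.41 (limma, adjusted p = 0.000709), and the mitotic kinase Plk1 changed by -1.22. Of 30 genes of DNA synthesis and S phase 18 were lower and none higher, 21 lower when adjusted over the list alone, with a median of -0.47 (camera, adjusted p = 7.5e-14; adjusted p = 0.0268 with an estimated correlation). Pcna, the sliding clamp of DNA polymerase, changed by -0.77 and the helicase subunit Mcm3 by -0.44. MYC targets in ribosome biogenesis had 9 of 23 members lower and none higher, 11 lower and 1 higher when adjusted over the list alone, with a median of -0.41 (camera, adjusted p = 1.67e-06; adjusted p = 0.0365 with an estimated correlation); spermidine synthase, Srm, changed by -0.74 and ornithine decarboxylase, Odc1, by -0.95. The immediate early genes, a marker list for handling of the cells, fell in the same libraries, with a median log2 change of -1.19 (camera, adjusted p = 0.000946; adjusted p = 0.0934 with an estimated correlation).

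Genes of oxidative phosphorylation encoded in the nucleus were lower. Of 35 subunits of complexes II to V 11 were lower and none higher, 20 lower when adjusted over the list alone, with a median of -0.35 (camera, adjusted p = 3.32e-10; adjusted p = 0.124 with an estimated correlation). Cytochrome c, Cycs, went from 37.0 ± 1.14 to 23.3 ± 0.183 FPKM (SD, n = 3 each), a log2 change of -0.64, and the ATP synthase subunit Atp5a1 changed by -0.48. Of 36 complex I subunits 5 were lower, 12 when adjusted over the list alone, with a median of -0.23 (camera, adjusted p = 1.39e-06; adjusted p = 0.217 with an estimated correlation); Ndufs7 had a log2 change of -0.49 and Ndufb6 of -0.36, and leaving out single libraries ended both calls, for Ndufb6 any of the 6 and for Ndufs7 any but WT replicate 2 and Hspa9 cKO replicate 3. From transcript ends Ndufs7 had -1.70 and was not called, and Ndufb6 had -0.24 and was not called once each library's trend over transcript length and GC content was removed. The import machinery had 4 of 21 members lower, 6 when adjusted over the list alone, and a median of -0.33 (camera, adjusted p = 8.68e-05; adjusted p = 0.0515 with an estimated correlation). Tomm6 and Tomm7, small subunits of the outer membrane translocase, changed by -0.77 and -0.40. Neither call held without WT replicate 1 or Hspa9 cKO replicate 2 or 3, nor that of Tomm6 without WT replicate 2 or that of Tomm7 without Hspa9 cKO replicate 1. Tomm6 had -0.64 and was not called after removal of the length trend. The mitochondrial ribosome had 1 of 38 members lower, 1 also when adjusted over the list alone, and a median of -0.19 (camera, adjusted p = 9.9e-05; adjusted p = 0.124 with an estimated correlation). That member, Mrpl12, changed by -0.65, a call lost without WT replicate 1 or any 1 Hspa9 cKO library. Cytosolic ribosomal proteins had 2 of 45 lower, none when adjusted over the list alone, and a median of -0.21 (camera, adjusted p = 7.35e-06; adjusted p = 0.266 with an estimated correlation). Of these, Rps27l changed by -0.28 and Rps2 by -0.42; the call of Rps27l was lost without any 1 library and that of Rps2 without any but WT replicate 3. After removal of the length trend Rps27l had -0.16 and Rps2 -0.33, neither called. Short transcripts were lower as a class: the median log2 change was -0.15 over the 110 genes with transcripts of at most 500 nucleotides and 0.12 over the 1686 genes above 5000 nucleotides.

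Metabolic lists beyond the respiratory chain fell too. Cholesterol synthesis had 7 of 21 members lower and none higher, 8 lower when adjusted over the list alone, with a median of -0.28 (camera, adjusted p = 1.63e-05; adjusted p = 0.0438 with an estimated correlation); Cyp51, lanosterol demethylase, changed by -0.57. Glycolysis had 6 of 20 members lower and 1 higher, also when adjusted over the list alone, with a median of -0.32 (camera, adjusted p = 0.00101; adjusted p = 0.0618 with an estimated correlation). Pgk1 and Ldha, of this list, changed by -0.55 and -0.57; from transcript ends alone Ldha had -0.45 and was not called, nor was the list. Hk1, a hexokinase, was the member higher, at 0.30, and lost its call without any 1 of the 6 libraries and after either rescaling. NRF2 and antioxidant genes had 4 of 18 lower, 6 lower and 1 higher when adjusted over the list alone, and a median of -0.20 (camera, adjusted p = 0.00356; adjusted p = 0.086 with an estimated correlation); G6pdx, of this list, had a log2 change of -0.59 and lost its call without Hspa9 cKO replicate 3. Gpx1, a glutathione peroxidase, had -0.33 and lost its call without WT replicate 1 or any 1 Hspa9 cKO library; from its transcript ends it had -3.22 and was not called.

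Genes that mark the DN3 stage were higher. The list of DN3 identity and V(D)J recombination had 8 of 22 members higher and 1 lower, 9 and 1 when adjusted over the list alone, with a median of 0.34 (camera, adjusted p = 0.0124; adjusted p = 0.17 with an estimated correlation). Notch targets had 5 of 15 higher and none lower, 8 higher when adjusted over the list alone, with a median of 0.26 (camera, adjusted p = 0.00627; adjusted p = 0.0877 with an estimated correlation); Il2ra, Ptcra and Hes1 are members of both lists. Il2ra, which encodes the sorting marker CD25, went from 152.8 ± 6.76 to 376.8 ± 9.01 FPKM (SD, n = 3 each), a log2 change of 1.30 (limma, adjusted p = 0.000617). Dtx1, a direct Notch target, changed by 1.45 and the CD3 subunit Cd3g by 0.54, while Dntt, the terminal transferase, had -0.26 and lost its call without any 1 of the 6 libraries, as well as with no filter on low genes and with the tables' own gene IDs. The list of the pre-TCR signal response and passage to DN4 was not called by camera (adjusted p = 0.0592; fry, adjusted p = 0.00342), with 1 of 18 members higher and 4 lower, also when adjusted over the list alone. Of these, the early response gene Nr4a1 had a log2 change of -1.30 and Cd8b1 of -1.1. Nr4a1 also belongs to the immediate early list, which fell. Slc3a2, an amino acid transporter subunit that the stress response list also holds, had 0.43 and kept its call only without WT replicate 3.

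The lists of p53 targets (6 higher and 1 lower of 17, also when adjusted over the list alone; camera, adjusted p = 0.0637) and of pyroptosis and necroptosis (3 higher of 10, also when adjusted over the list alone; adjusted p = 0.0637) were not called. Ccng1, a p53 target, had a log2 change of 0.70, Bbc3, which encodes the death protein PUMA, of 0.93 and Gtse1 of -0.78. The call of Bbc3 was lost without Hspa9 cKO replicate 1 or 3 and that of Gtse1 without any library but Hspa9 cKO replicate 1. The inflammatory caspases Casp1 and Casp4 had 0.83 and 0.92; the call of Casp1 was lost without any 1 Hspa9 cKO library and that of Casp4 without any library but WT replicate 3. From transcript starts Gtse1 had -0.69 and was not called, and with a pseudocount of 0.1 Casp4 had 2.19 and was not called. Neither were DN1 and DN2 progenitor genes (adjusted p = 0.115), iron-sulfur cluster and heme synthesis (0.138), calcium transfer between endoplasmic reticulum and mitochondria (0.646), hypoxia (0.774), apoptosis regulators (0.774), mitochondrial DNA maintenance (0.774), mitochondrial dynamics and mitophagy (0.823) or NF-kB targets (0.983), all by camera. The lists of calcium transfer, hypoxia, apoptosis and NF-kB had medians of 0.05, 0.04, 0.09 and 0.14 while camera, which compares a list with all other genes, placed them downward. The median over all tested genes was 0.064, below those of apoptosis and NF-kB, so medians alone do not give the direction for these lists. The only called member of each was lower, Birc5 (log2 change -1.11) and Tnfaip3 (-1.68). Among genes of mitochondrial dynamics and mitophagy, Mief2 had a log2 change of 0.59 and Bnip3l of 0.38; the call of Mief2 was lost without WT replicate 1 or any 1 Hspa9 cKO library and that of Bnip3l without any 1 library.

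**Figure D3:**
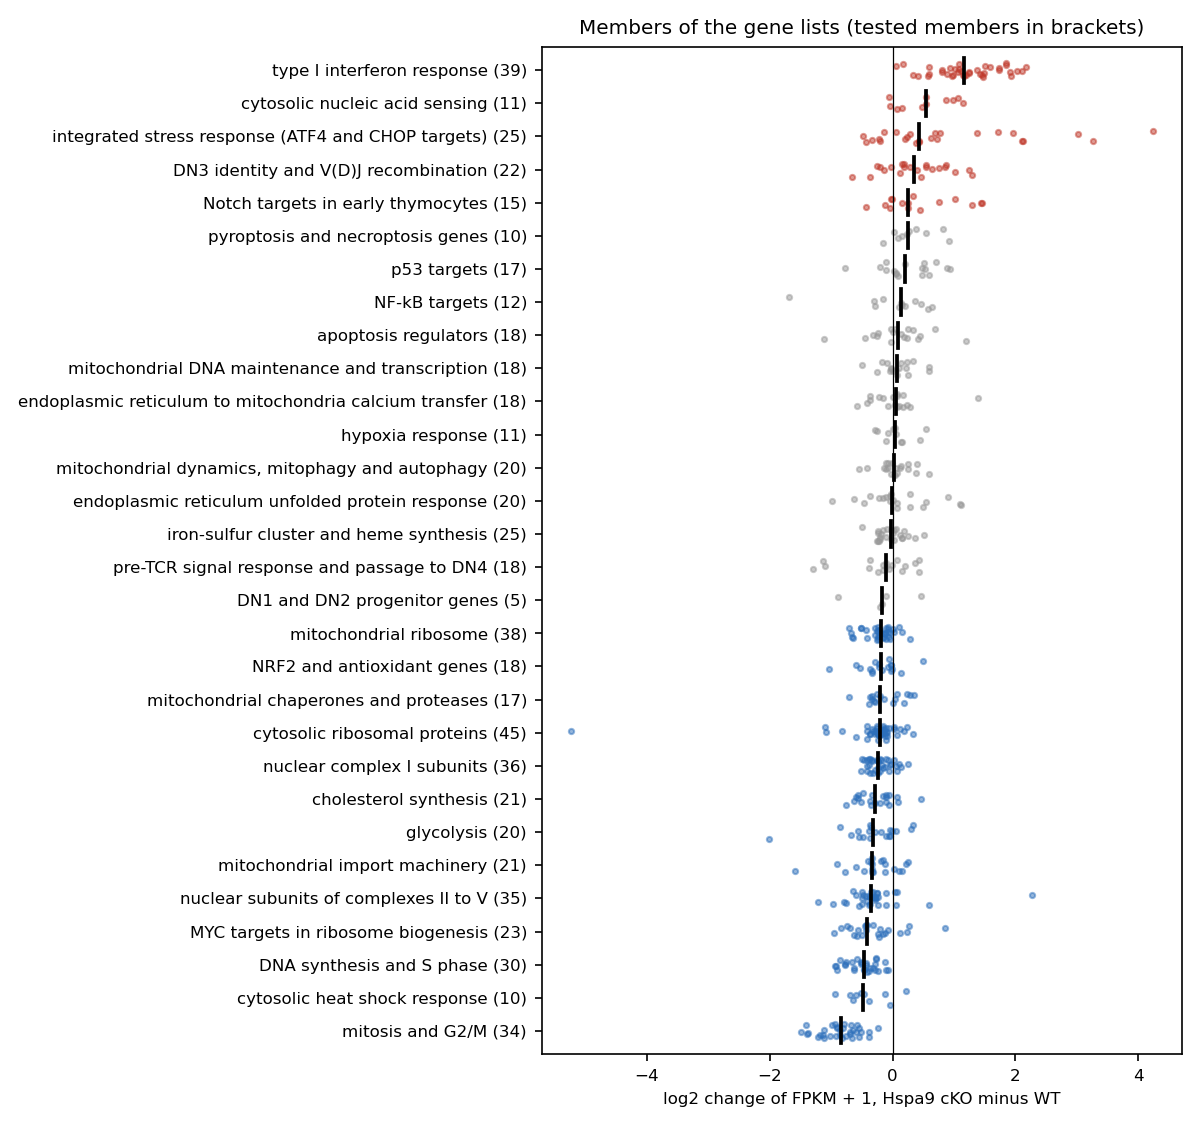
Log2 change of FPKM + 1 (Hspa9 cKO minus WT, horizontal axis) for the tested members of 30 gene lists; points are genes, black bars are list medians, red and blue mark lists called upward and downward by camera with an inter-gene correlation of 0.01, and grey marks lists not called. Medians run from -0.83 for mitosis to 1.17 for the interferon response.

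The fourth comparison asked whether markers of other cell types differed. Of 13 marker lists 5 had at least 5 tested members, and only the list of dissociation and immediate early genes was called (camera, adjusted p = 0.000946; adjusted p = 0.0934 with an estimated correlation). Of its 6 members 4 were lower, 4 also when adjusted over the list alone: Fosb, Nr4a1, Fos (log2 change -1.08) and Dusp1 (-1.29). Egr1, at 8.77 ± 0.948 FPKM in WT and 9.82 ± 1.05 FPKM in Hspa9 cKO, and Ier3, at 2.08 ± 0.361 and 2.28 ± 0.504 FPKM (SD, n = 3 each), were not called. The lists of gamma-delta T cells (camera, adjusted p = 0.903), double-positive thymocytes (0.903), mature single-positive T cells (0.326) and sex-linked transcripts (0.359) were not called. By fry 3 marker lists passed: immediate early genes (adjusted p = 0.000154), double-positive thymocytes and mature single-positive T cells (0.0358 for both). Within the double-positive list members went both ways: Aqp11 and Arpp21 had log2 changes of 0.71 and 0.65 and Cd8b1 of -1.1. From transcript starts Arpp21 had 0.19 and was not called. Cd4, Cd8a and Trac, abundant in double-positive cells, averaged at most 1.22 FPKM in either group. Of the single-positive list, Gimap6 had 0.66 and Klf2 0.49, the latter a call lost without any 1 library and from transcript ends (0.23). Among genes of natural killer and innate lymphoid cells, Gzma fell from 177.5 ± 8.29 FPKM in WT to 145.0 ± 2.75 in Hspa9 cKO and Id2 from 13.8 ± 1.5 to 7.01 ± 0.909, while Nkg7 rose from 31.2 ± 1.66 to 59.1 ± 2.15 (FPKM, SD, n = 3 each; limma, adjusted p = 0.0355, 0.0096 and 0.00202). The call of Gzma was lost without any 1 library. Of macrophage and dendritic cell genes the most abundant were Lyz2, at 12.4 ± 3.17 and 14.3 ± 0.992 FPKM, and H2-Ab1, at 6.06 ± 1.1 and 5.55 ± 0.278 FPKM (SD, n = 3 each), neither called. The hemoglobin gene Hba-a2, near-identical to Hba-a1 and so uncertain, fell from 29.4 ± 3.15 to 17.3 ± 1.17 FPKM (SD, n = 3 each; limma, adjusted p = 0.00993), and Hbb-bt, another hemoglobin gene, had a log2 change of -0.53 (limma, adjusted p = 0.0322). The hemoglobin genes Hba-a1 (log2 change -0.59; limma, adjusted p = 0.0865) and Hbb-bs (-0.02, adjusted p = 0.978) were not called. Cd79b, a B cell receptor subunit, rose from 11.4 ± 1.48 to 17.0 ± 1.54 FPKM (limma, adjusted p = 0.037) and Epcam, an epithelial adhesion molecule, from 27.9 ± 1.03 to 39.2 ± 3.35 FPKM (adjusted p = 0.0199; SD, n = 3 each). Cpa3, a mast cell protease, fell from 9.85 ± 0.438 to 6.64 ± 0.560 FPKM (SD, n = 3 each; limma, adjusted p = 0.0218); no member of the neutrophil list reached the filter.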

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

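Only the pooled tests of a transcript length trend and the tests of other splits of the libraries were set before their results were seen; the tests of other cell types and cell stages, and the count of unassigned events, were chosen after. Start events that matched no annotated gene, which no comparison above uses, were more numerous in Hspa9 cKO: 720.3 ± 21.5 were listed per library against 580.7 ± 20.8 in WT (SD, n = 3 each; exact two-sided permutation test, p = 0.1, the smallest possible), while assigned start events differed by a factor of 1.03.

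The interferon list rose in Hspa9 cKO. Macrophages or dendritic cells left in the Hspa9 cKO sort are one technical explanation. The 6 markers of these cells with a mean of at least 1 FPKM had a median log2 change of -0.07 (SD 0.30), against the list's 1.17, and the most abundant, Lyz2, was at 12.4 and 14.3 FPKM, which argues against it. The sort is described as lineage-negative, though its purity is not given. Still open are a response to interferon or nucleic acid within the sorted cells under the genotype, and a difference between the animals or their housing. Neither of these could be tested. Other lymphocytes in the sort were not tested as a source either. Of the innate lymphoid genes Nkg7 rose while Gzma and Id2 fell. The mature single-positive list was called by fry (adjusted p = 0.0358) but not by camera (adjusted p = 0.326).

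The mitosis list fell in Hspa9 cKO. Double-positive thymocytes in the WT sort would bring Cd4, Cd8a and Trac, which reached at most 1.34 FPKM in a WT library, and Aqp11, also a gene of those cells, was higher in Hspa9 cKO; both argue against them as the source, although Cd8b1 moved the other way. Fewer cells past the pre-TCR signal, within the DN3 gate, could lower cell cycle genes and raise Il2ra. The list of that passage had a camera adjusted p of 0.059 with a median log2 change of -0.11, and fry, which makes no comparison with other genes, called it (adjusted p = 0.00342). This shift in cell stage therefore cannot be told apart from slower cycling at the same stage, since each library is a mixture. Nr4a1 (log2 change -1.30) and Egr1 (0.15, not called) of that list also belong to the immediate early list, a marker of handling that fell. A difference in handling thus stays open as well.

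Lists of short transcripts fell in Hspa9 cKO, and a trend over transcript length and GC content between libraries is a technical explanation. After its removal the median log2 change went from -0.23 to -0.14 (standard error 0.039) for complex I, from -0.35 to -0.25 (0.116) for complexes II to V, from -0.21 to -0.10 (0.149) for cytosolic and from -0.19 to -0.13 (0.045) for mitochondrial ribosomal proteins. Camera at a correlation of 0.01 still called the 4 lists (adjusted p = 0.000574, 1.74e-08, 0.00469 and 0.00168), but with an estimated correlation none was called even before the removal (adjusted p = 0.217, 0.124, 0.266 and 0.124). The test set in advance pooled the lists in pairs and asked that they stay called and keep most of their change. Both pairs met it: oxidative phosphorylation went from -0.28 to -0.20 and ribosomal proteins from -0.21 to -0.12. With a margin of the standard error also required, the oxidative phosphorylation pair passed narrowly (0.06) and the ribosomal pair did not (0.083). No list by itself passed that bound by more than its standard error. The trend therefore cannot be told apart from a fall of these genes. The requirement on the standard error and the reading by list came after the values were seen, and an effect of the genotype stays open.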

How the results depend on the processing

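The alternatives with start or end events alone, the tables' own gene IDs, the principal edge and the length trend, fry for marker lists, and all tests of splicing, were chosen after the data were seen. The count of 1344 called genes was 240 with the replicate block, 307 in the test against a 1.2-fold change and 521 to 882 with 1 library left out, which leaves fewer samples; under the other settings it lay between 992 and 1407. Each of the 1344 genes kept its direction in every setting fixed in advance that tested it. Because their groups do not overlap, only the rescalings among these settings could have reversed a direction. From end events alone 991 of the 1012 tested kept their sign, and from start events alone 1295 of 1298. The replicate numbers do not pair the libraries: deviations from the group means correlated by -0.004, 0.002 and -0.023 for numbers 1, 2 and 3, and 0 of the 6 libraries correlated best with their own number. The block changed no list call. The 18 called lists were 6 with an estimated correlation, 22 by fry, without cytosolic ribosomal proteins (adjusted p 0.0681), and 17 to 20 otherwise. Over 306 list values recomputed under settings other than these set tests, 305 kept direction and call, and glycolysis lost its call with end events alone (median log2 change -0.17). The marker count of 1 became 0 with an estimated correlation and 3 by fry. The Hspa9 level in cKO against WT, never called, had a log2 change of -0.041 after rescaling by trimmed means and of -0.036 by median ratios, and of -0.057 to 0.054 with 1 library left out, against 0.01 as reported (adjusted p 0.952). The Hspa9 exon inclusion in cKO against WT differed by -68.7 to -75.67 percentage points with 1 library left out. The rule chose 76 genes besides Hspa9; 50 stayed called without each library in turn, 26 did not, and of 1261 recomputed values 174 were no longer called and 1 reversed, Tuba1a with end events alone (0.18). The 20 called splicing ratios became 72 with a pseudocount of 0.1, 10 with a mean total of 1 FPKM, 0 with the replicate block and 0 to 10 with 1 library left out; the cause was not tested for any of these changes. Count tests were not run because the tables hold no counts.

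With 3 libraries per group there are 10 splits, too few for a share under 0.05. The real split gave 1344 genes and the highest other 6 (1 of the 10 splits gave as many); for lists 18 and 11 (1 split), for marker lists 1 and 1 (2 splits), and for splicing ratios 20 and 6 (1 split). Unknown depth limits what can be said of low genes.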

Other observations

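The tests of gene families and of splicing were chosen after the data were seen; the sex-linked transcripts were listed before. Genes were grouped by the leading letters of their symbols into 149 families with at least 8 tested members, and 25 were called by camera at an inter-gene correlation of 0.01, but 0 with an estimated correlation (lowest adjusted p = 0.424). Among the 253 Zfp zinc finger genes, mostly DNA-binding proteins, 32 were higher and 2 lower, with a median log2 change of 0.31 (camera, adjusted p = 0.000233), and 0.26 after the trend over transcript length and GC content was removed. The 22 H2- genes of the histocompatibility complex, near-identical in part, had 9 higher and 2 lower with a median of 0.58 (adjusted p = 0.00612). The 24 Kif kinesin motors had 10 lower and 1 higher with a median of -0.31 (adjusted p = 0.000233). The 14 Psmd subunits of the proteasome had 3 lower and a median of -0.24 (adjusted p = 0.00731). The 21 Trbv segments had 3 lower and a median of -0.35 (adjusted p = 0.00165), a call lost after that trend was removed (adjusted p = 0.0956).

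Of 10573 splicing ratios 20 were called (limma), 14 toward inclusion, while 953 had an unadjusted p under 0.05 where chance would give 529. The count was 10, 3 and 9 without WT replicate 1, 2 or 3 and 6, 5 and 0 without Hspa9 cKO replicate 1, 2 or 3. The retained intron of Lck, the kinase of pre-TCR signaling, at 129556747 to 129557034 on chromosome 4 of mm10, took 12.5% ± 2.0 (SD, n = 3) of its paired FPKM in WT and was not listed in Hspa9 cKO (limma, adjusted p = 0.00388). Retention of the Sf3b1 intron at 55014562 to 55016376 on chromosome 1 was 0.149% ± 0.0133 in WT and 24.4% ± 2.13 in Hspa9 cKO (SD, n = 3 each; limma, adjusted p = 0.00612). The paired event retaining several introns over the same Sf3b1 positions had shares of 18.9% ± 2.26 and 98.0% ± 0.0493 (SD, n = 3 each). Ivns1abp went from 100% in each WT library to 0% in each Hspa9 cKO library for the intron at 151355311 to 151355850 on chromosome 1, with no spread, at a mean total of 9 FPKM. Another called Ivns1abp intron, at 151356236 to 151359622, went the other way, from no listed retention in WT to 90.2% ± 16.9 in Hspa9 cKO (SD, n = 3; limma, adjusted p = 0.0211).

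Transcripts of both sexes were found in every library. RNA of a single animal would not hold both, so the libraries may be pools of animals or hold RNA of other samples, which the labels do not state. Xist, made in female cells, was at 62.2, 53.7 and 50.4 FPKM in WT replicates 1 to 3 and at 71.6, 74.3 and 69.3 FPKM in Hspa9 cKO replicates 1 to 3, a log2 change of 0.37 (limma, adjusted p = 0.0508). Ddx3y, on the Y chromosome, lay between 3.10 and 5.30 FPKM. Uty, also on the Y chromosome, was at 0.452 ± 0.428 FPKM in WT and 1.63 ± 0.261 FPKM in Hspa9 cKO (SD, n = 3 each; limma, adjusted p = 0.0655) and was not listed in WT replicate 3. Of the 5 sex-linked transcripts none was called over all genes tested and 2 were higher when adjusted over the list alone.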
